A study of Mus musculus with 6 samples.

How the data were processed

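Total RNA was isolated with TRIzol from cochleae of male DBA/2J mice aged 7 weeks (n = 3 samples) and 36 weeks (n = 3 samples), converted to biotin-labelled cRNA by in vitro transcription and hybridised to Affymetrix arrays, 1 array per sample, per the labels' protocols. The deposited values are intensity values, that is, linear probe-set signals of 1 colour. The software that summarised the probes is not given in the sources used here. From the values themselves, the arrays had been scaled to a common trimmed mean, which lay between 1489.9 and 1492.8 on all 6 arrays with the lowest 2% and the values above the 98th percentile left out. The values were not on a log scale and genes were not centred. Their absolute scale remains unknown. Per the series design text, the submitters set each young sample against each old one, 9 pairs in all, and carried out no replicate arrays, quality control or dye swap.

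Probe sets were named from the platform annotation. Of 22626 probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had none, and only the first kind was named. The Entrez identifier of 20351 probe sets was found in the RefSeq gene table of assembly GRCm38.p6, which was used for names alone and updated 0 symbols. No coordinates were used. A gene with several tested probe sets was represented by the brightest. Probe sets whose names end in _x_at or _s_at can bind transcripts of related genes. Those of Igha, H2-D1, H2-K1, H2-Ab1, Hspa1b, Hadh, Rps29, Rrm2, Psmc2, Slc4a1, Ndufa13, Uqcrq, Atp5c1, Atp5e, Mcm7, Dbp, S100a1, Acta2, Sdhc, Ighm, Fkbp11, Bpifb1 and Slc25a5 are of this kind, and their identity is less certain.

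The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. Signals were transformed as log2(signal + 50), which understates the change of dim probe sets. Where the mean signal of an age was dim, well below the array medians of 766.3 to 859.4, the size of a log2 difference or fold depends on the floor of the signal and on the offset. The 13575 probe sets whose mean over the 6 arrays was above the 40th percentile were tested with lmFit and eBayes (intensity trend) of limma, 36 weeks minus 7 weeks, unpaired as in the design text and two-sided. A Benjamini-Hochberg adjusted p under 0.05 was the threshold. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so it was not used for single genes.

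Before the data were examined, 39 gene lists were fixed for energy metabolism, stress, immune and matrix pathways, for cochlear cell types and for other cell types that a dissected cochlea can hold, such as bone, marrow, blood, muscle and brain. The 38 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. All adjusted p-values given for lists come from this test unless an estimated correlation is named. Counts adjusted over the list alone apply the adjustment to a list's own members in place of all probe sets.

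The genes named were set by a rule, also fixed in advance. Per direction it takes the 12 genes with the largest log2 difference among probe sets past the threshold with all 9 pairs in one direction. Of each called list it takes the 4 members with the smallest p in the list's direction, and of every other list the 2 members with the smallest p. It names only probe sets with 1 symbol, each gene by its brightest tested probe set, and mentions other probe sets of a gene that pass in the opposite direction. Members named beyond the rule, where a count was 5 or fewer or a gene was singled out (Myo7a, Myo15, Tmc1, Myo6, Otof), were chosen after their values were seen.

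The test was tried on simulated data for this comparison. With 200 of 13575 probe sets changed, it recovered 58% of those changed by a log2 value of 1 and 10% of those changed by 0.5, with 1 false call in 69. In the data 33.6% of the tested probe sets passed, and the adjusted threshold is less strict where more change. The recovered shares therefore do not give the power of the real comparison. A simulated list shifted by 0.4 was called and 0 unshifted lists were called. Genes were simulated as independent, so this does not cover false calls of lists whose genes are correlated. The median standard deviation within an age fell from 0.44 on the log2 scale among the dimmest probe sets to 0.09 at 7 weeks and 0.07 at 36 weeks among the brightest.

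The alternatives planned in advance were offsets of 1 and 16, quantile normalization, centring on the array median, no filter or a filter at the 60th percentile, eBayes without the intensity trend, the replicate number as a block, each array left out in turn, the 9 pairs with a 1.5-fold minimum, genes as the unit of counting, camera with an estimated correlation, fry and the mean of all probe sets of a gene. Those added after seeing the data were a 2-fold minimum, lists without genes of more than 1 list, respiratory lists without muscle-type subunits, and sensory neuron genes without members of a list fixed in advance. Lists for pituitary gland, secretory mucosa, ciliated epithelium, peripheral sensory neurons, brown fat and mitochondrial isoforms were also written after the values had been seen, and were set against 10000 random lists of the same size and signal.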

Results

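Gene expression was measured in the cochlea, the hearing organ of the inner ear, of male DBA/2J mice, an inbred strain that loses hearing early in life. Total RNA from 3 samples taken at 7 weeks of age and 3 samples taken at 36 weeks was hybridised to 6 single-colour Affymetrix arrays, 1 array per sample. The table held a linear signal for 22626 probe sets on each array. The median signal was 799.9, 766.3 and 800.5 on the arrays of 7 weeks and 859.4, 844.0 and 847.4 on those of 36 weeks. The number of arrays limits the precision of every value below. The comparison asked which transcripts differ between the young cochlea and the cochlea at an age when the strain has lost hearing. All log2 differences are 36 weeks minus 7 weeks, each with its standard error (SE) and n = 3 arrays per age, and folds are ratios of the mean signals.

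Transcripts of the granulocyte lineage were far higher at 36 weeks, while those of spiral ligament fibrocytes, supporting cells, the stria vascularis, myelin and skeletal muscle were lower. The neutrophil and granulocyte precursor genes rose by a median log2 difference of 3.75, with 17 of 17 measured members past the test. The spiral ligament fibrocyte genes fell by a median of 1.13 and the skeletal muscle genes by 1.58. Genes of respiratory complex I fell by a smaller amount, with a median of -0.43. Hair cell genes were not past the test as a group. By limma with Benjamini-Hochberg adjustment, 4558 of 13575 tested probe sets passed the threshold, 2203 higher and 2355 lower at 36 weeks. Of these, 632 were at least 2-fold higher and 521 at least 2-fold lower. Counted by gene, 1457 of 8541 genes were higher and 1471 were lower. All 9 pairs of a young and an old array pointed in one direction for 6417 probe sets (47.3%, against 10% by chance).

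Among the named genes, the largest rise was that of Hp, the haemoglobin-binding plasma protein haptoglobin, whose mean signal went from 231.5 to 10159, a log2 difference of 5.42 ± 0.38. Its signal at 7 weeks was dim, with a standard deviation of 210.6, as were those of Reg3g, Ucp1 and Agr2 (392.6, 164.5 and 338.9), so the sizes of these rises depend on the floor of the signal and on the offset (5.82 for Hp with an offset of 1). Reg3g, an antibacterial lectin, rose by 5.08 ± 0.30 and Gp2, a membrane glycoprotein of secretory granules, by 4.85 ± 0.15. Lcn2, the iron-sequestering lipocalin, rose by 4.80 ± 0.11, from a signal of 1055 to 30498. Tff2, a trefoil peptide secreted with mucus, rose 23.1-fold to 115985, and Muc5b, a gel-forming mucin, rose 18.3-fold to 78734. Agr2, a disulfide isomerase of mucus-secreting cells, rose by 4.18 ± 0.20. Pglyrp1 and Camp, antibacterial proteins of granulocytes, rose by 4.73 ± 0.08 and 4.45 ± 0.15. Igha, the heavy chain of immunoglobulin A, rose by 4.24 ± 0.14, and Ucp1, the uncoupling protein of brown fat, by 4.25 ± 0.28 from a dim 164.5. Gh, growth hormone of the anterior pituitary, rose by 4.06 ± 0.08, from 3802 to 64172. These rises came in the same comparison as the granulocyte list median of 3.75. For these 12 genes the largest adjusted p was 1.87e-06, that of Hp.

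Among the named genes that fell, the largest fall was that of Epyc, a small leucine-rich proteoglycan, which went from a signal of 16545 to 1294, a log2 difference of -3.63 ± 0.09. Col9a3, a chain of type IX collagen, fell by 3.06 ± 0.28. Otos, otospiralin of the fibrocytes, fell 5.36-fold from 73912 to 13801, with a log2 difference of -2.42 ± 0.06. Vip, a neuropeptide, fell by 2.95 ± 0.13, and Mepe, a matrix phosphoglycoprotein of osteocytes, by 2.64 ± 0.45. Genes of striated muscle made up the other 7. Sln, the regulator of the muscle calcium pump, fell by 3.52 ± 0.26 and Myl1, a myosin light chain, by 3.12 ± 0.14. Pgam2, the muscle phosphoglycerate mutase, Myh7 and Myl2, of slow muscle myosin, had log2 differences of -2.94, -2.75 and -2.75. Ckmt2, the sarcomeric mitochondrial creatine kinase, and Trdn, triadin of the muscle calcium release complex, both had -2.49. The signals of Col9a3, Mepe and Sln at 36 weeks were dim (226.6, 286.9 and 277.8). Those of Pgam2, Myh7 and Myl2 were also below the array medians (463.2, 461.4 and 550.6). The sizes of the falls of these genes therefore depend on the floor of the signal and on the offset. The largest adjusted p among these 12 genes was 0.00109, that of Mepe.

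**Figure D1:**
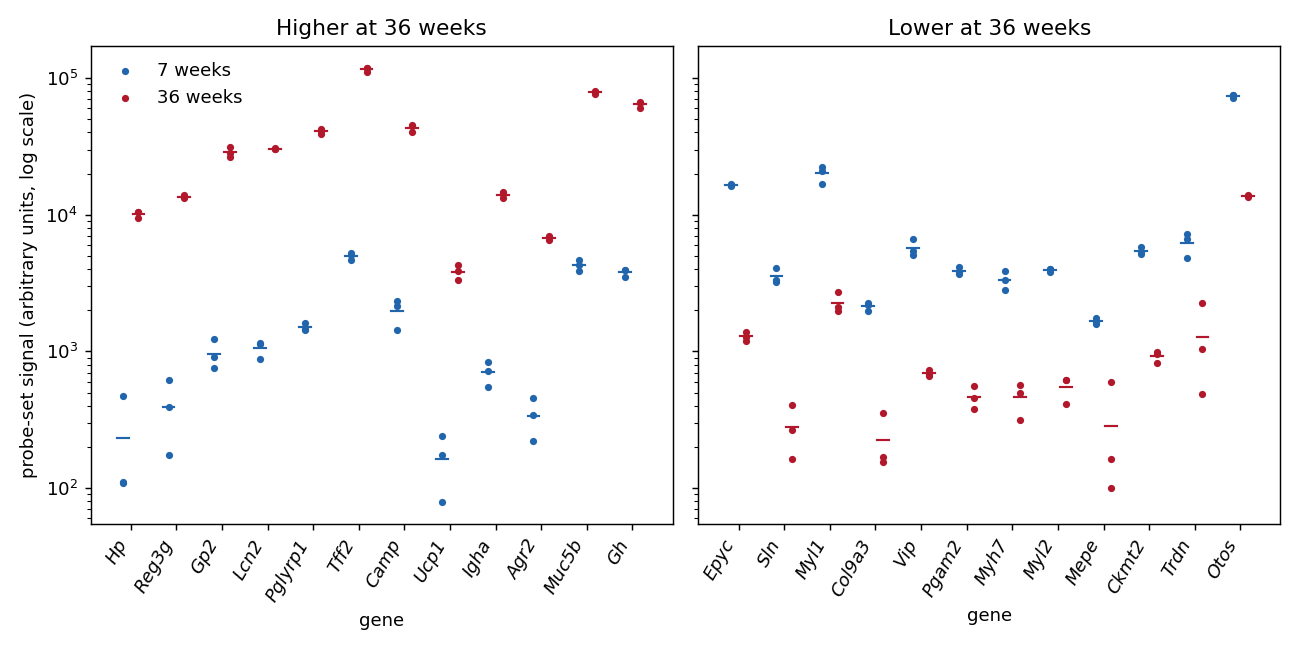
Probe-set signal (arbitrary units, log axis) of the 12 genes with the largest rise and the 12 with the largest fall, 1 point per array and a bar at the mean of the 3 arrays of 7 weeks (blue) and of 36 weeks (red). The arrays of each age lie apart from those of the other age in every gene shown, for example 3802 against 64172 on average for Gh.

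Granulocyte and macrophage genes were higher at 36 weeks. In the neutrophil and granulocyte precursor list 17 of 17 rose (17 adjusted over the list alone), with a camera adjusted p of 4.85e-18. S100a9, a calcium-binding alarmin of neutrophils, rose 13.4-fold to a signal of 180095. Ltf, lactoferrin, Mpo, myeloperoxidase, and Ngp, a granule protein, rose 12.6-fold, 14.9-fold and 15.3-fold. Lcn2 and Ltf of this list are also made by secretory epithelium. Of 23 macrophage genes 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.55 and an adjusted p of 1.27e-06. Lyz2, lysozyme, rose by 2.66 ± 0.05, Tyrobp, a signalling adaptor, by 2.31 ± 0.09, Ptprc, the pan-leukocyte antigen CD45, by 3.10 ± 0.15 and Cd53, a leukocyte tetraspanin, by 2.01 ± 0.17. These 4 are also expressed by granulocytes. Of 14 B lineage genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), short of the threshold with an adjusted p of 0.0562. Jchain, the joining chain of secreted immunoglobulin, rose by 3.77 ± 0.25 from a dim 219.1, which leaves its size dependent on the floor, Igk by 1.44 ± 0.23, Ighm by 0.58 and Cd37 by 0.89, while Ebf1, a transcription factor also found in mesenchyme, fell by 1.00. The T and NK cell list had 3 measured genes, too few for the list test. Of these Il2rb rose by 1.29 (also adjusted over the list alone), and Thy1 and Zap70 differed by 0.24 and 0.33 without passing.

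Antigen presentation genes rose, 7 of 14 with 0 falling (10 and 0 adjusted over the list alone), with a median of 0.43 and an adjusted p of 0.000938 (adjusted p = 0.0564 with an estimated correlation). H2-D1 and H2-K1, class I molecules, rose by 1.84 ± 0.08 and 0.57 ± 0.08, Cd74, the class II invariant chain, by 0.91 ± 0.08 and H2-Ab1, a class II chain, by 0.68 ± 0.14. The granulocyte and macrophage lists, medians 3.75 and 0.55, were higher on the same arrays. The complement and inflammation list was not past the test (median 0.34, adjusted p of 0.223), with 4 of 13 rising and 2 falling (5 and 2 adjusted over the list alone). Ccl9, a chemokine of myeloid cells, rose by 2.64 ± 0.28, Il1b by 1.19, Ccl5 by 0.99 and Cd14 by 0.35, whereas Nfkbia, the inhibitor of NF-kappa-B, fell by 0.44 ± 0.06 and Serping1 by 0.37. Interferon-response genes went both ways, 3 rising and 4 falling of 17 (3 and 4 adjusted over the list alone), with an adjusted p of 0.742 and a median of 0.01 and mean of 0.01 against a test direction of lower. Ifi35 rose by 0.77 ± 0.12, Stat2 by 1.14 and Oas1a by 0.51, and Rsad2, viperin, fell by 0.66 ± 0.12, Ifit3 by 0.70, Irgm1 by 0.77 and Ifit1 by 0.52.

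Transcripts of the cochlear lateral wall were lower at 36 weeks. Of 17 spiral ligament fibrocyte genes 16 fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -1.13 and an adjusted p of 4.62e-10. Coch, cochlin, a matrix protein whose mutation causes deafness, went from a signal of 82144 to 21556, a log2 difference of -1.93 ± 0.06, beside the fall of Otos. Gjb2 and Gjb6, the connexins of cochlear gap junctions, fell 3.71-fold and 4.11-fold. The member that rose was Vim, vimentin, by 0.36, which many other cell types express. Of 15 stria vascularis genes 8 fell and 1, Kit, rose by 0.44 (9 and 1 adjusted over the list alone), with a median of -0.98 and an adjusted p of 4.88e-05. Slc26a4, pendrin, the anion exchanger, fell by 2.28 ± 0.10, and Dct and Mitf, genes of the pigment cell lineage, by 2.10 ± 0.09 and 1.80 ± 0.15. Slc12a2, the sodium-potassium-chloride cotransporter of marginal cells and fibrocytes, fell by 1.24 ± 0.07. The granulocyte list median of 3.75 and the skeletal muscle median of -1.58 stood on the same arrays as these lists. Because the arrays had been scaled to a common trimmed mean, the signals are relative. A smaller share of lateral wall RNA at 36 weeks cannot be told apart from lower levels in its cells. The same holds for the supporting cell and myelin lists below.

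In the supporting cell and tectorial membrane list 13 of 19 fell and 1, Lfng, rose by 0.51 (14 and 1 adjusted over the list alone), with a median of -0.95 and an adjusted p of 9.22e-07. Besides Epyc, Gjb2 and Gjb6, S100a1, a calcium-binding protein also abundant in muscle, fell 4.56-fold from a signal of 42737. Hair cell genes showed no shared direction. Of 13 measured, 2 rose, 4 fell and 7 did not pass (2 and 4 adjusted over the list alone), and the adjusted p was 0.957. Calb2, calretinin, fell by 1.14 ± 0.09 and Ush1c, harmonin of the hair bundle, fell by 2.35 ± 0.37 to a dim 395.1. Myo6 fell by 0.92 and Otof, otoferlin of the inner hair cell synapse, by 0.40. Calb1 rose by 0.65 and Atp2b2, a plasma membrane calcium pump, by 0.66. Cerebellar neurons also express both, and the brain tissue list rose by a median of 1.02 in the same comparison. The hair cell median was 0.23, while its mean of -0.14 and the test had the opposite sign. Myo7a, Myo15 and Tmc1, which serve mechanotransduction, had log2 differences of 0.35, 0.23 and -0.08 and did not pass.

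Neuronal genes were higher and myelin genes lower at 36 weeks. Of 36 genes in the spiral ganglion neuron list 16 rose and 6 fell (17 and 6 adjusted over the list alone), with a median of 0.46 and an adjusted p of 0.0072 (adjusted p = 0.0824 with an estimated correlation). Prph, the intermediate filament peripherin, rose 5.82-fold, Stmn2 rose by 1.14 ± 0.07, Sncg by 1.22 ± 0.09 and Uchl1 by 0.98 ± 0.09, all genes shared by many neurons. The brain tissue list rose too, 10 of 16 with 0 falling (11 and 1 adjusted over the list alone), with an adjusted p of 1.27e-06. Its leading members, Cbln1, Gabra6, Neurod1 and Aldoc, with log2 differences of 2.54, 2.24, 2.17 and 1.73, are genes of cerebellar neurons or glia. With only probe sets above the 60th percentile, the spiral ganglion list had a median of 0.12 and an adjusted p of 0.0647. Of 14 Schwann cell and myelin genes 10 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.74 and an adjusted p of 3.10e-05. S100b fell by 1.69 ± 0.09, Pmp22, a protein of peripheral myelin, by 1.07 ± 0.06, and Cryab, a small heat shock protein also abundant in muscle, by 1.24 ± 0.09. Ugt8a, which makes myelin galactolipids, fell 2.89-fold.

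Skeletal muscle and mitochondrial genes were lower at 36 weeks. Of 23 skeletal muscle genes 21 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of -1.58 and an adjusted p of 1.38e-16. Acta1, skeletal actin, fell 3.15-fold from a signal of 51865, and the troponins Tnni2 and Tnnc2 and the myosin light chain Mylpf fell 3.85-fold, 3.26-fold and 5.03-fold. Of 33 complex I genes 25 fell and 0 rose (25 and 0 adjusted over the list alone), with a median of -0.43 and an adjusted p of 8.90e-08. Ndufb9, Ndufa13, Ndufb11 and Ndufb2 fell by 0.87 ± 0.07, 0.79 ± 0.08, 0.94 ± 0.10 and 0.74 ± 0.08. Of 14 genes of complexes II and III 11 fell and 1, Sdhc, measured by a probe set that can bind related transcripts, rose by 0.47 (11 and 1 adjusted over the list alone), with a median of -0.45 and an adjusted p of 0.000938 (adjusted p = 0.185 with an estimated correlation). Uqcr11 fell by 0.89 ± 0.09, Cyc1, cytochrome c1, by 0.67 ± 0.07, Uqcrb by 0.44 ± 0.06 and Uqcrq by 0.55 ± 0.07. A dimmer probe set of Uqcrq rose by 0.70. Of 17 complex IV genes 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.34 and an adjusted p of 0.00018 (adjusted p = 0.0921 with an estimated correlation). Its leading members Cox7a1, Cox8b and Cox6a2 are subunits of heart and skeletal muscle and fell 3.69-fold, 2.99-fold and 2.90-fold, while Cox6c fell 1.59-fold. Without these muscle subunits, an alternative chosen after seeing the data, the complex IV median was -0.34 and the adjusted p 0.0064. Of 17 ATP synthase genes 13 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.46 and an adjusted p of 3.10e-05 (adjusted p = 0.101 with an estimated correlation). Atp5j, Atp5c1, Atp5e and Atp5g3 fell by 0.79, 0.67, 0.86 and 0.44.

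Of 18 genes of the tricarboxylic acid (TCA) cycle 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.48 and an adjusted p of 9.53e-05 (adjusted p = 0.0564 with an estimated correlation). Idh2, Mdh2, Idh3a and Fh1 fell by 0.93, 0.63, 0.67 and 0.67. Fatty acid oxidation genes were at the edge of the threshold, 6 of 18 falling and 0 rising (9 and 0 adjusted over the list alone), with a median of -0.25 and an adjusted p of 0.0501. Hadh fell by 0.40 ± 0.07 and Etfa by 0.50 ± 0.09. Glycolytic enzymes went both ways, 5 rising and 8 falling of 16 (5 and 8 adjusted over the list alone), with a median of -0.19 and an adjusted p of 0.237. Aldoc, the brain aldolase, rose by 1.73 ± 0.06 while the muscle enzyme Pgam2 fell by 2.94 ± 0.16. The other members that rose were Eno2, the neuronal enolase, by 0.49, Pfkp by 0.44, Pkm by 0.33 and Hk1 by 0.32. The skeletal muscle list fell by a median of 1.58 on the same arrays as all of these lists.

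Cell cycle genes rose, 15 of 21 with 0 falling (18 and 1 adjusted over the list alone), with a median of 0.64 and an adjusted p of 1.57e-05. Plk1, a mitotic kinase, rose by 1.13 ± 0.23, Top2a, a topoisomerase of dividing cells, by 0.91 ± 0.19, Rrm2, a subunit of ribonucleotide reductase, by 0.70 ± 0.14 and Mcm7, of the replicative helicase, by 0.48 ± 0.10. The granulocyte list, which includes genes of dividing marrow precursors such as Mpo, rose beside them by a median of 3.75. The circadian clock list fell, 10 of 12 with 0 rising (10 and 0 adjusted over the list alone), with a median of -0.61 and an adjusted p of 0.000125 (adjusted p = 0.0564 with an estimated correlation). Dbp, a clock-controlled transcription factor, fell 3.88-fold, Cry2 3.14-fold to a dim 377.2, Nr1d2 2.03-fold and Per3 1.61-fold. The labels give no hour of tissue collection. Heat shock and unfolded protein response genes fell, 13 of 27 with 3 rising (13 and 3 adjusted over the list alone), with a median of -0.18 and an adjusted p of 0.00618 (adjusted p = 0.0709 with an estimated correlation). Hspa1b, an inducible chaperone, fell by 1.54 ± 0.10, Hspa9, of mitochondria, by 0.74 ± 0.10, Dnajb1 by 0.81 ± 0.11 and Cryab by 1.24 ± 0.09, while Xbp1, a transcription factor of secretory cells, rose by 0.82, Calr by 0.40 and Hspb1 by 0.36. After quantile normalization the adjusted p of this list was 0.0559.

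Proteasome genes fell slightly, 7 of 31 with 2 rising (5 and 1 adjusted over the list alone), with a median of -0.19 and an adjusted p of 0.0269 (adjusted p = 0.0987 with an estimated correlation). Psmc2, Psma3, Psmd12 and Psmd1 fell by 0.48, 0.47, 0.48 and 0.33, and Psmd2 and Psmb1 rose by 0.36 and 0.29. The proteasome call ended with quantile normalization (adjusted p of 0.135), with the filter at the 60th percentile (0.0672) and without 36 weeks replicate 1 (0.0538), and that of Psmd1 ended without 36 weeks replicate 1 (0.0733), without 7 weeks replicate 3 (0.0708) and without the intensity trend (0.0635). Cytosolic ribosome genes were not past the test, 2 rising and 7 falling of 34 (2 and 7 adjusted over the list alone), with a median of -0.12 and an adjusted p of 0.0736. Rps29 fell by 0.34 ± 0.06, Rplp0 rose by 0.47 ± 0.09 and Rps15 rose by 0.25. Of 15 cholesterol synthesis genes 5 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.16 and an adjusted p of 0.165. Hmgcs1, which makes the precursor of mevalonate, fell by 1.19 ± 0.13, Msmo1 by 1.07 ± 0.15, Idi1 by 1.17, Cyp51 by 0.89 and Nsdhl by 0.34.

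Antioxidant enzymes went both ways, 7 rising and 8 falling of 23 (7 and 9 adjusted over the list alone), with a median of -0.13 and an adjusted p of 0.673. Gsta4, a glutathione transferase that clears lipid peroxidation products, fell 3.92-fold, and Gsr, glutathione reductase, rose 2.57-fold. Apoptosis genes did so too, 5 rising and 4 falling of 23 (5 and 4 adjusted over the list alone), with an adjusted p of 0.957 and a median of 0.06 against a mean of -0.06 and a test direction of lower. Aifm1, a mitochondrial flavoprotein, and Bad, a pro-apoptotic Bcl-2 family member, fell by 0.70 ± 0.14 and 1.39 ± 0.36, Birc2 by 0.57 and Bcl2l1, an anti-apoptotic member, by 0.55. Apaf1, of the apoptosome, rose by 0.83, Birc3 by 0.48, Dffa by 0.43, Diablo by 0.35 and Tnfrsf1a by 0.30. Immediate early genes had 5 rising and 7 falling of 21 (8 and 7 adjusted over the list alone), with an adjusted p of 0.764 and a median of 0.12 against a mean of -0.17 and a test direction of lower. Egr2 and Egr1, zinc finger transcription factors, fell by 1.26 ± 0.13 and 1.16 ± 0.14, and Nr4a1, Nr4a2, Ier2, Btg2 and Jund rose by 0.73, 0.69, 0.66, 0.42 and 0.25. The granulocyte median of 3.75 and the muscle median of -1.58 also stood beside these pathway lists.

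Osteoblast, cartilage and extracellular matrix genes were lower at 36 weeks. Of 14 osteoblast and osteocyte genes 8 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.69 and an adjusted p of 0.00242 (adjusted p = 0.0656 with an estimated correlation). Dmp1, a matrix protein of osteocytes, fell by 1.35 ± 0.17, Col5a2 by 1.04 ± 0.11, Sparc, osteonectin, by 0.76 ± 0.06 and Col1a2 by 0.62 ± 0.06, while Col1a1 rose by 0.53 and Fkbp11, a gene of secretory cells, by 0.79. Of 12 cartilage genes 8 fell and 3 rose (8 and 3 adjusted over the list alone), with a median of -0.92 and an adjusted p of 0.0141 (adjusted p = 0.117 with an estimated correlation). Cnmd, chondromodulin, fell 5.41-fold, Col9a1 fell 3.27-fold and Col11a2 2.13-fold, and Col9a3 fell to a dim 226.6. The members that rose were Prg4, lubricin of joint surfaces, by 2.50, Chad by 1.34 and Comp by 1.08. The cartilage call ended without 7 weeks replicate 2 (median -0.66, adjusted p of 0.0574) and without 7 weeks replicate 3 (median -0.58, adjusted p of 0.0949). Of 33 extracellular matrix genes 16 fell and 2 rose (17 and 4 adjusted over the list alone), with a median of -0.48 and an adjusted p of 0.000741 (adjusted p = 0.0564 with an estimated correlation). Col3a1, Plod2, Timp3 and Dcn fell by 1.57, 1.61, 1.31 and 1.02, and Fn1, fibronectin, and Fbln2 rose by 0.49 and 0.51. Of 9 osteoclast genes 2 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.23 and an adjusted p of 0.385. Mmp9, a gelatinase also stored by neutrophils, rose 4.24-fold, Oscar rose by 0.63 and Car2, carbonic anhydrase, fell 1.75-fold. The muscle and granulocyte medians of -1.58 and 3.75 applied to the same arrays.

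Of 11 smooth muscle and pericyte genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.50 and an adjusted p of 0.0029 (adjusted p = 0.0964 with an estimated correlation), beside the skeletal muscle median of -1.58. Myl9, Tagln and Acta2, of the contractile apparatus, and Pdgfrb, a pericyte receptor, fell by 1.09, 1.10, 0.77 and 1.29. Endothelial genes were not past the test, 2 of 17 rising and 0 falling (1 and 0 adjusted over the list alone), with a median of 0.05 and an adjusted p of 0.445. Vwf, von Willebrand factor, rose by 0.88 ± 0.19 and Ets1 by 0.53 ± 0.18, and the call of Ets1 (adjusted p of 0.0466) ended under 8 alternatives, with adjusted p from 0.0577 to 0.164, among them leaving out either of 7 weeks replicates 1 (0.0964) and 2 (0.134) or any of 36 weeks replicates 1 (0.0704), 2 (0.0617) and 3 (0.164). Of 14 erythroid genes 1 rose and 3 fell (1 and 3 adjusted over the list alone), with a median of -0.06 and an adjusted p of 0.299. Slc4a1, the red cell anion exchanger, fell by 1.89 ± 0.13, Car2 by 0.81 ± 0.08 and Ermap by 1.02, and Epor rose by 0.40. Of 9 adipocyte genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.32 and an adjusted p of 0.195. Besides Ucp1, Fabp4, the fatty acid binding protein of adipocytes, rose by 1.30 ± 0.13, Cidea by 1.03 and Adipoq, adiponectin, by 0.87, and Scd1 fell by 0.39.

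**Figure D2:**
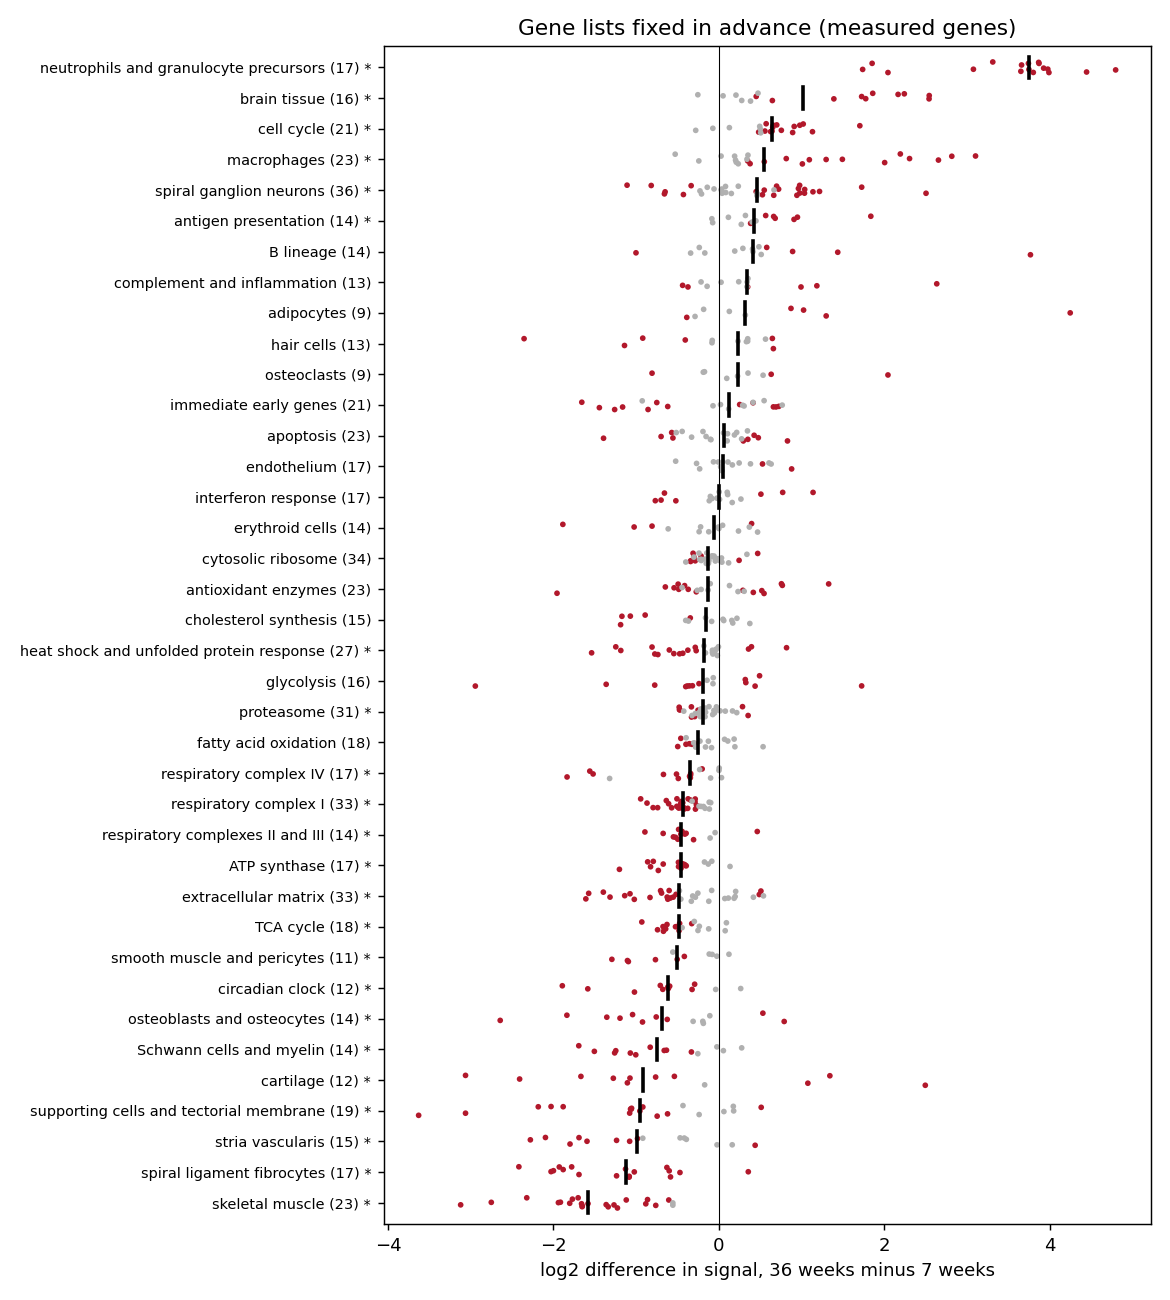
Log2 difference in signal (36 weeks minus 7 weeks) of each measured gene in the 38 tested lists, 1 point per gene, red where the gene passed the threshold, with a black bar at the list median. The number of measured genes stands in brackets and an asterisk marks lists past the threshold of the list test. The neutrophil list lies highest, with a median of 3.75, and the skeletal muscle list lowest, with -1.58.

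The list test called 23 of 38 lists, and 10 lists were called with an estimated correlation between genes. The labels do not say that the arrays of an age came from separate animals, so the p-values measure only the spread between these samples, which may be technical. No processing batch or date was given, so none could be told apart from age.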

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

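Across the fits with other offsets, scalings, filters, variance models or 1 array fewer, between 3641 and 4593 probe sets passed the limma threshold, against 4558 in the report. With 1 array left out the count lay between 3641 and 4041. As the replicate block, the replicate number gave 4297 probe sets, 2071 higher and 2226 lower, and 23 lists. The deviations of same-numbered arrays from their group means correlated by 0.0480, -0.0135 and -0.00304, so the numbers do not pair the arrays. The 9 pairs with a 1.5-fold minimum gave 2969 probe sets, 1410 of them lower, genes in place of probe sets gave 2928, 1457 higher and 1471 lower, and a 2-fold minimum, chosen after seeing the data, gave 1153, 632 higher and 521 lower. Camera with an estimated correlation called 10 lists in place of 23, which by construction rests on the few residual degrees of freedom of 6 arrays. Fry, which asks only whether the genes of a list move on balance one way, called 33. With 1 array left out camera called between 22 and 25 lists, and without genes of more than 1 list it called 23. Of the 136 named genes, 134 passed under every alternative fit that kept their probe set, the exceptions being Psmd1 and Ets1. The filter at the 60th percentile left out dim named genes, Ucp1, Col9a3 and Mepe among them, so these were not tested there. Of the 23 lists, 19 were called under every alternative fit set out in advance other than the estimated correlation, the exceptions being heat shock, proteasome, spiral ganglion neurons and cartilage. The fatty acid oxidation, cytosolic ribosome and B lineage lists passed under some alternatives, with adjusted p down to 0.0204, 0.0262 and 0.0244. The cause of these changes was not tested. No called list and no named gene changed direction under the alternatives run. The balance of calls, with fewer higher than lower in the report, turned without the intensity trend (2039 higher and 2030 lower), without 7 weeks replicate 1 (1998 and 1967), replicate 2 (1834 and 1807) or replicate 3 (2040 and 2001), and with the 9 pairs (1559 and 1410) and the 2-fold minimum. The median log2 difference of all tested probe sets, 0.02, changed sign to -0.02 with quantile normalization, with median centring and with the filter at the 60th percentile. Of the 10 ways to split the 6 arrays into 3 and 3, 1, the real one, gave as many probe sets past the threshold (4558, 2203 higher and 2355 lower) and as many lists (23). Under limma the other splits gave 0 probe sets, with 126 to 266 at an unadjusted p under 0.05 against 5920. They gave up to 19 lists. Each of them parts 2 arrays of an age from the other and so keeps 0.333 of the age difference, and list medians in them were 0.308 to 0.368 of the real ones. With 10 splits no share under 0.05 can be reached. Dim probe sets limit the precision, with a within-age standard deviation of 0.44 log2 units at the lowest signals.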

Other observations

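The lists for other tissues were written after the results of the comparison had been seen, with members not yet looked at kept apart, and the test of within-age spread was chosen only after its result was seen. Hormone genes of the anterior pituitary were higher at 36 weeks. Prl, prolactin, rose from a signal of 688.3 to 9551 and Cga, the shared glycoprotein hormone chain, from a dim 144.2 to 3082, beside Gh. Pomc rose by 0.56 and Lhb by 0.74, while Chga, Pitx1 and Lhx3 had log2 differences of 0.11, 0.45 and 0.33 and did not pass the limma test. Genes of secretory mucosa chosen for their size all rose, 13 of 13. Bpifb1, a secreted airway protein, rose from 58392 to 226319, and Bpifa1 was bright at both ages, at 85220 and 113323. Among members not looked at before, Dmbt1, a mucosal glycoprotein, rose by 2.66, Slpi, a secreted protease inhibitor, by 2.27, Wfdc2 by 1.89 and Aqp5, the water channel of glands, by 1.87. Epcam, an epithelial adhesion molecule, fell by 0.37.

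Genes of peripheral sensory neurons were higher as well. Scn11a, a sodium channel of nociceptors, went from a dim 157.8, with a standard deviation of 182.6, to 2517, and its log2 difference of 3.99 ± 0.50 depends on the floor of the signal. Avil, advillin, rose by 2.70, Calcb, a form of calcitonin gene-related peptide, by 1.63, Ret by 1.41 and Tlx3 by 1.37, while Isl1 (-0.29) and Gal (0.01) did not pass. Of 5 ciliated epithelium genes 1 rose, Tppp3 by 1.51, and 2 fell, Mlf1 by 1.23 and Rsph1 by 0.76, with a median of -0.09 at percentile 28.5 of the random lists. Of 5 brown fat genes other than Ucp1, Cidea rose by 1.03 and Fabp3 and Ppargc1a fell by 1.03 and 0.76, with a median of 0.25 at percentile 84.3.

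Transcripts of some other tissues were higher at 36 weeks, while the lists for skeletal muscle, cartilage, osteoblasts and smooth muscle were lower, with medians of -1.58, -0.92, -0.69 and -0.50. Of these calls only that of skeletal muscle was kept with an estimated correlation (adjusted p = 0.117, 0.0656 and 0.0964 with an estimated correlation for the other lists), and that of cartilage also ended without 7 weeks replicate 2 (median -0.66, adjusted p of 0.0574) or 3 (median -0.58, adjusted p of 0.0949). A candidate explanation for the rises is a dissection that took in other tissue at that age, though not more skeletal muscle. Members not looked at before had medians of 0.43 for pituitary gland (15 genes, 5 rising and 2 falling), 0.59 for secretory mucosa (22 genes, 13 rising and 1 falling) and 0.98 for peripheral sensory neurons without Sncg of the spiral ganglion list (14 genes, 9 rising and 0 falling). These lay at percentiles 99.8, 100 and 100 of 10000 random lists, so each of the 3 sources remained possible, as did an untested change with age in the tissue itself, such as infiltration or middle ear inflammation. The pituitary members that rose were Chgb, Pcsk1n, Scg3, Dlk1 and Pcsk1 (0.62, 1.01, 1.49, 1.33 and 1.27, the last from a dim 420.7). Cpe and Nnat fell by 0.38 and 0.44. Scg5, Scg2, Gata2, Crhr1, Ghrhr, Nr5a1, Drd2 and Tbx19 did not pass, with log2 differences of 0.05, 0.27, -0.22, 0.43, 0.51, 0.69, 0.18 and -0.01. The brain tissue list also rose, by a median of 1.02.

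The respiratory chain lists were lower at 36 weeks together with skeletal muscle, but with an estimated correlation complex I alone among them kept its call (adjusted p = 0.185, 0.0921 and 0.101 with an estimated correlation for complexes II and III, complex IV and ATP synthase). The median log2 difference of all tested probe sets was 0.02, against -0.43 for complex I. That median covers dim and bright probe sets together. It therefore cannot show how far uneven scaling of bright probe sets lowered complex I. Under quantile normalization and median centring the complex I median nearest to 0 was -0.37. Both settings level the bulk of the probe sets, so they cannot show whether a changed mix of RNA lowered these lists. If less muscle RNA were the whole cause, isoforms outside muscle should have stayed near 0. Muscle-type isoforms fell in 5 of 5 cases, with a median of -1.56 at percentile 0.01 of the random lists. The 5 widely expressed isoforms had a median of -0.17 at percentile 58.3, which was not unusual for genes of that signal. The bounds of the test made no allowance for this. Among these isoforms Cox7a2 and Ckmt1 fell by 0.34 and 0.54, and Cox6a1, Slc25a5 and Cox8a were at -0.10, -0.17 and 0.03. Ckmt2, Cox6a2, Cox8b and Cox7a1 had already been seen to fall, and Cox7a2, Cox6a1 and Cox8a belonged to the tested complex IV list. The fall of the muscle-type isoforms was therefore no independent test. The median of the widely expressed isoforms lay between the bounds, which were set before the test but after the comparison had been seen. So less muscle and a lower level in the cochlea itself, as age could bring, cannot be told apart. Other explanations were not tested, and the granulocyte list rose by a median of 3.75 on the same arrays.

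Arrays of one age varied little, with correlations of log2 signal between 0.957 and 0.960 within an age and between 0.842 and 0.852 across ages. A candidate explanation is that the arrays of an age shared a pool of RNA, since separate dissections should differ in the amount of muscle, mucosa, marrow or pituitary. The test used 55 genes of those tissues that passed the threshold with at least a 2-fold change. Their median ratio of the within-age standard deviation to that of genes of like signal was 1.08. Passing the threshold favours genes of small within-age spread, and the genes of like signal were not chosen so. The ratio therefore cannot show that excess spread was absent. Very even dissection of separate animals, or pools of several animals per array, would give the same value and stay open.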
